A study of Ambystoma mexicanum with 22 samples.

How the data were processed

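RNA was sequenced from cells of axolotl (Ambystoma mexicanum) blastemas, the mounds of progenitor cells that rebuild an amputated limb. Per the labels, an upper limb was amputated, and a nanoparticle carrying rhodamine, GalNP(Rho), was injected 48 hours before collection. Blastemas were taken at 11 days (early bud), 13 days (mid bud), 15 days (late bud) and 18 days (palette) after amputation. Probes of this type release their dye where lysosomal beta-galactosidase is active, an activity widely used as a marker of senescent cells. Live cells, taking up calcein and excluding SYTOX, were sorted by rhodamine signal, with vehicle-injected blastemas setting the gate. Per the labels, the rhodamine-positive fraction (Rho+) holds senescent cells and the rhodamine-negative fraction (Rho-) holds non-senescent cells. Libraries were made per the labels' protocols by a modified Smart-seq2 procedure, with poly-dT capture and amplification of the cDNA, and sequenced as single-end reads. The 22 libraries come from 11 animals, each of which gave 1 Rho- and 1 Rho+ library. Each fraction has 3 libraries at the early bud, 2 at the mid bud, 3 at the late bud and 3 at the palette. No animal appears at more than 1 stage. A mid bud replicate 3 was not analysed here.

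The authors deposited a table of raw counts per gene, not normalised, with a column for each library. Per the submitters' processing notes, the tools were bcl2fastq 2.20.0, STAR 2.7.6a and featureCounts 2.0.1. The genome build, the strand setting and the treatment of reads with several alignments are not given in the sources used here. The identifiers of the count table carry the AMEX60DD prefix, and coordinates are given as the table gives them, by chromosome arm. The table has 99205 entries, of which 92 are ERCC spike-in sequences with a count of 0 in every library. Of the remaining 99113 loci, 24 lie on the mitochondrial genome, 57838 have no symbol, 16761 have a LOC number and 18876 have another symbol. Symbols and descriptions were taken from the table itself. The description sometimes belongs to an unrelated protein of the same name: CHK1 is described as a carbohydrate kinase, GLB1 as a nitrogen regulatory protein, and LEP as an integrase-type DNA-binding protein. A gene's identity therefore rests on its symbol, and CHK1, a symbol shared by 35 loci, is not taken here for the checkpoint kinase. Genes whose symbol is shared by several loci are uncertain, since reads can be split among near-identical copies. Overlapping genes on opposite strands cannot be told apart if the counting ignored strand.

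Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test with robust dispersion, after TMM normalisation. One model with a mean for each of the 8 groups was fitted to the 22 libraries, so that all comparisons share an estimate of the spread. Loci were kept by filterByExpr with a minimum count of 10, which left 22424 loci. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Levels are CPM values computed from the effective library size after TMM, and are given as mean ± SD over libraries. The change over all stages is the mean of the 4 stage differences on the log2 scale, so every stage has the same weight whatever its number of animals. Standard errors of log2 changes were derived from the F statistic. A change against a group at 0 depends on the prior count and is no bound. For such genes a lower bound was computed against 3 counts summed over the group, and intervals for ratios on 1 to 3 counts are exact binomial intervals at 95%. These bounds and intervals cover counting error only, since amplified reads without molecular identifiers are not independent molecules. The comparisons were Rho+ against Rho- over all stages and at each stage, the stage dependence of that difference, and the palette against the early bud within each fraction.

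Before the data were examined, 27 gene lists were fixed. They cover senescence and cell cycle arrest, the secretory phenotype of senescent cells, lysosome, proliferation, WNT ligands, WNT pathway targets and feedback, FGF, BMP, TGF-beta, hedgehog and other growth signals, connective tissue and blastema progenitor, cartilage and bone, and fibrillar collagen and matrix. Lists for other cells were macrophage and monocyte, osteoclast, neutrophil and granulocyte, lymphocyte, epidermis, endothelium and pericyte, skeletal muscle, Schwann and nerve, erythroid and pigment cell. The remaining lists were immediate early and heat shock, interferon and antigen presentation, complement and coagulation, lipid handling, oxidative phosphorylation, ribosomal protein and housekeeping. Symbols were matched exactly, taking the locus with the highest mean where several share a symbol. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the 27 lists, with an estimated correlation and with fry beside it. Camera compares a list with all other genes. Some genes stand in several lists.

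The rule for named genes, fixed at the same time, took loci with a symbol, an adjusted p under 0.05, a mean of at least 5 CPM in the higher fraction and the same sign in at least 10 of 11 animals. Of these, the 12 largest changes each way were taken. For a single stage the rule required the same sign in every animal and took the 4 largest each way. For stage dependence it took the 6 smallest p-values, and for palette against early bud the 6 largest each way among genes whose groups did not overlap. Where no gene passed, the 5 smallest p-values were taken, and up to 4 members of each list described were named by smallest p. A panel was reported whatever its values: GLB1, CDKN1A, CDKN1B, CDKN1C, CDKN2B, TP53, MKI67, PCNA, LMNB1 and the WNT ligands. CDKN1C, CDKN2B and PCNA had no exact match among the symbols. A further choice, restricted to genes with 1 locus and several exon blocks, was made after the values were seen, because most of the rule's higher genes were single-exon loci or shared symbols.

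Pairing of the libraries comes from the animal number in the labels. The correlation of deviations from the group means between the paired libraries of an animal was checked and ranged from -0.193 to 0.144, with a median of -0.0271. Within groups, the correlation of log2 CPM between replicates ranged from 0.567 to 0.89, and no libraries held identical counts. The fit with the animal as a block was chosen as an alternative at that time, and called 414 genes over all stages against 1462 without it. For palette against early bud, where no animal is in both stages, the replicate number took the place of the animal. Also chosen then were DESeq2 size factors, no filter, a stricter filter with a minimum count of 50, the DESeq2 1.42.0 test, limma voom with quality weights, the compared libraries alone, and each library left out in turn. Alternatives chosen after seeing the data were the omission of mitochondrial counts, thinning of every library to 2587152 non-mitochondrial counts, the omission of 2 or 3 doubted libraries, and looser symbol matching. Differences between the paired libraries of animals were tested by exact two-sided sign-flip tests.

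The procedure was tested on simulated data for the comparison over all stages, with 200 changed genes among 21137. It recovered 24% of genes changed 4-fold and 71% of genes changed 16-fold, with median fitted log2 changes of 2.17 and 4.04. Of 104 genes called, 9 were unchanged ones, or 8.65%. Total counts per library ranged from 8737824 to 28499544.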

Results

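The series holds 22 RNA libraries of cells sorted from regenerating axolotl limbs, in 8 groups set by stage and rhodamine fraction. Counts per library totalled 21170000 ± 3879000 in Rho- and 13990000 ± 3279000 in Rho+ (SD, n = 11 each), and were lower in Rho+ in 11 of 11 animals (exact two-sided sign-flip test, p = 0.000977, adjusted p = 0.00244 over 10 library measures). The range ran from 8737824 in late bud Rho+ replicate 2 to 28499544 in palette Rho- replicate 3.

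Mitochondrial transcripts, nearly all of them ribosomal RNA, separated the fractions. Their share was 30.9 ± 11.9% of counts in Rho- and 66.2 ± 10.2% in Rho+, higher in Rho+ in 10 of 11 animals (exact two-sided sign-flip test, p = 0.00195, adjusted p = 0.00279). The exception was the animal of replicate 3 at the early bud, whose Rho- library held 60.5% and whose Rho+ library held 49.8%. Counts outside the mitochondrial genome were 14680000 ± 3624000 in Rho- and 4711000 ± 1781000 in Rho+. Loci with at least 10 counts numbered 15940 ± 2319 in Rho- and 11700 ± 1151 in Rho+ (adjusted p = 0.00279 by the same exact test). Loci with a lone exon took 2.90 ± 0.35% of non-mitochondrial counts in Rho- and 5.03 ± 1.19% in Rho+, higher in 11 of 11 animals (exact test, adjusted p = 0.00244).

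**Figure D1:**
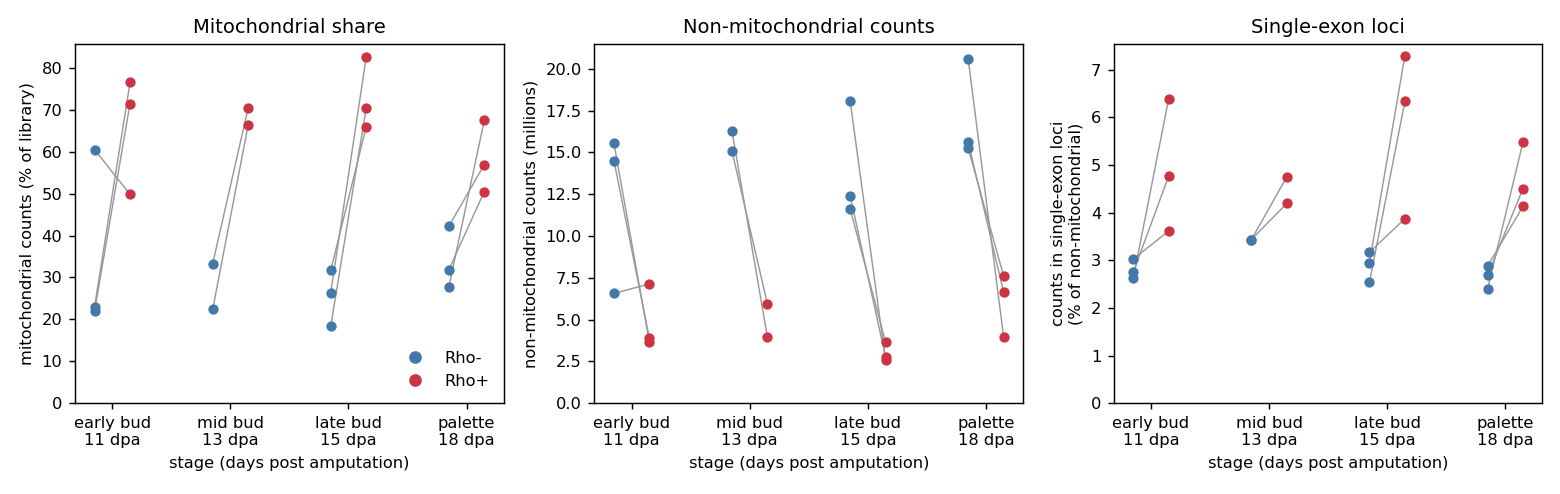
Share of mitochondrial counts (% of the library), non-mitochondrial counts (in units of 1e+06) and share of single-exon loci (% of non-mitochondrial counts) for each library, by stage. Each point is a library, blue for Rho- and red for Rho+, and grey lines join the paired libraries of an animal; 10 of 11 animals had the higher mitochondrial share in Rho+.

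The comparison of Rho+ with Rho- over all stages asked what distinguishes senescent cells of the blastema from their non-senescent neighbours. Some genes of macrophages and lysosomes, such as CD68 and ASAH1, rose in Rho+, and some genes of the extracellular matrix, of connective tissue, of cartilage and of WNT and FGF signalling fell. CD68, a lysosomal membrane protein of macrophages (AMEX60DD012740, arm 1p, 79266480 to 79417235), rose from 53.6 ± 39.2 CPM in Rho- to 285 ± 233 CPM in Rho+ (SD, n = 11 each, log2 change 2.42, SE 0.40, adjusted p = 0.000963; 11 of 11 animals). SELENOP, a secreted selenium carrier (AMEX60DD041991, arm 6p, 376756224 to 376782531), rose from 539 ± 346 to 2455 ± 1677 CPM (log2 change 2.17, SE 0.36, adjusted p = 0.00211; 11 of 11 animals). IRF8, a transcription factor of the monocyte lineage, rose from 4.39 ± 5.30 to 19.6 ± 30.3 CPM (log2 change 3.59, SE 0.81, adjusted p = 0.00938; 10 of 11 animals). FN1, which encodes fibronectin, fell from 1089 ± 666 to 275 ± 169 CPM (log2 change -1.80, SE 0.35, adjusted p = 0.0042; 10 of 11 animals lower). WIF1, a secreted inhibitor of WNT ligands (AMEX60DD008217, arm 12q, 769437726 to 769809196), fell from 11.3 ± 14.2 to 0.156 ± 0.308 CPM (adjusted p = 0.00291; 10 of 11 animals lower). FGF16, a fibroblast growth factor, fell from 13.2 ± 9.61 to 0.60 ± 0.906 CPM (adjusted p = 0.00329). CD68 and SELENOP were chosen after their values were seen; IRF8, WIF1 and FGF16 were taken by the rule.

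Of 22424 loci, 1462 passed, 985 higher and 477 lower in Rho+ (edgeR quasi-likelihood test). The median log2 change of all genes was -0.251 with TMM and 0.008 with DESeq2 size factors, under which 1204 loci were higher and 252 lower, so that changes are to be read against that median. With the animal as a block, 414 genes passed, 270 higher and 144 lower, of which 388 were among the 1462. The count was 143, 227, 782 and 877 without mid bud Rho- replicate 1, Rho- replicate 2, Rho+ replicate 1 and Rho+ replicate 2, each of which leaves 1 library in its group. The alternatives were tallied for 75 of the named or listed genes past the threshold, not for all of them. List members such as SFRP1, LAMB1, COL6A1 and BGN also passed but were not among the 75. Of the 75, 62 lost the threshold without some mid bud library and 13 kept it in every alternative that tested them. The 13 were CD68, MYL1 and 2 CHK1 loci among the higher ones, and FBLN1, FN1, WIF1, FGF16, COL2A1, S1PR1, RNF43, TBC1D24.1.L and HoxD11 among the lower ones. MYL1 was not higher at each stage. It stood at 109 ± 87.6 CPM in Rho- and 17.9 ± 11.9 in Rho+ at the early bud, and its palette Rho- group was at 0. SELENOP reached an adjusted p of 0.0512 without mid bud Rho- replicate 2, and IRF8 reached 0.0979 and 0.102 without mid bud Rho- replicate 1 and replicate 2.

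Among the remaining genes of the rule, S1PR1, a receptor for sphingosine 1-phosphate, fell from 6.51 ± 4.81 to 0.485 ± 1.09 CPM, lower in 11 of 11 animals (adjusted p = 0.00537). RNF43, a ubiquitin ligase that removes WNT receptors, fell from 7.44 ± 5.43 to 1.41 ± 1.99 CPM (adjusted p = 0.00611), and MN1, a transcriptional coregulator, from 9.07 ± 6.80 to 1.73 ± 5.01 CPM (adjusted p = 0.00889). TBC1D24.1.L fell by 3.77 on the log2 scale (SE 0.80, adjusted p = 0.00644) and the locus with the symbol RIC3 by 4.87 (SE 1.18, adjusted p = 0.0144). NLRC3, a NOD-like receptor by its symbol, at a locus of a lone exon, rose from 0.531 ± 0.711 to 6.94 ± 4.39 CPM (log2 change 4.15, SE 0.97, adjusted p = 0.0117). PTH1R, the parathyroid hormone receptor, MXRA8, TMEM237, NDNF and PEAR1 also fell, and TRIOBP, UBR4, FOXO6, WEE2-AS1 and the mitochondrial tRNA-His rose, but none of these 10 passed with the animal as a block (adjusted p from 0.0523 to 0.0955, against 414 genes that did pass). Genes chosen after their values were seen included SLC11A1, a metal transporter of phagosomes, at 17.2 ± 15.3 CPM in Rho- and 107 ± 95.8 in Rho+ (adjusted p = 0.0263; 0.122 with the block). AOAH, a lipase that inactivates bacterial lipopolysaccharide, stood at 15.8 ± 13.3 and 65.6 ± 58.4 CPM (adjusted p = 0.0208; 0.179 with the block).

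**Figure D2:**
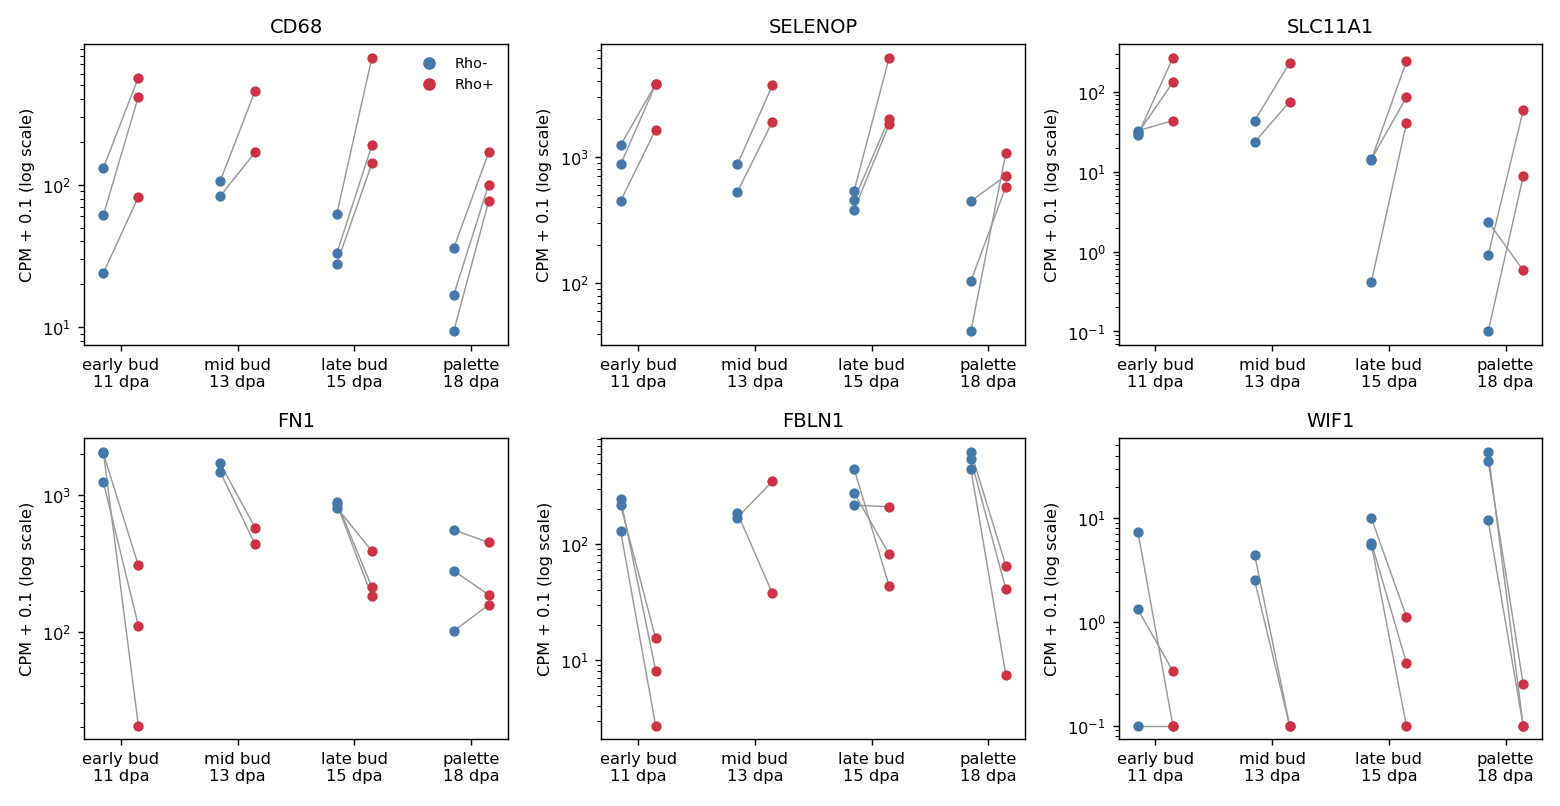
Levels of 6 genes in each library by stage, as CPM + 0.1 on a log axis. Points are libraries, blue for Rho- and red for Rho+, and grey lines join the paired libraries of an animal; CD68 and SELENOP were higher in Rho+ in 11 of 11 animals.

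Matrix genes formed the most broadly lowered group. Of 44 tested members of the fibrillar collagen and matrix list, 15 fell and 29 did not pass, and 24 fell when adjusted over the list alone. Their median log2 change was -1.14, or -1.16 with members at 0 in a group set to their bound (camera adjusted p = 5.12e-13, adjusted p = 0.151 with an estimated correlation). FBLN1, a fibulin of elastic fibres, fell from 317 to 78.0 CPM (log2 change -2.43, SE 0.41, adjusted p = 0.00105). SPARC, a collagen-binding glycoprotein, fell from 1333 to 541 CPM (log2 change -1.21, SE 0.29, adjusted p = 0.0141). After thinning to equal non-mitochondrial counts the log2 change of SPARC was -0.81 (adjusted p = 0.141). LOXL2, a collagen crosslinking enzyme, fell from 20.1 to 1.90 CPM (log2 change -3.63, SE 0.83, adjusted p = 0.0105). The connective tissue and blastema progenitor list had 5 of 39 members lower and 11 adjusted over the list alone (median -1.27; camera adjusted p = 6e-08, adjusted p = 0.114 with an estimated correlation). Its members included HoxD11, a positional gene of the distal limb, which fell from 21.9 to 7.24 CPM (adjusted p = 0.00681). In the cartilage and bone list 3 of 15 fell, COL2A1, COL9A2 and COL11A2, all collagens of cartilage, and 4 adjusted over the list alone (median -1.81, or -1.20 at the bound; camera adjusted p = 0.00283, adjusted p = 0.114 with an estimated correlation). COL2A1 (arm 3q, 375692686 to 375765573) fell from 94.9 to 35.9 CPM (adjusted p = 0.00363), and COL11A2 did not pass with the animal as a block (0.0854, among 414 that did). COL9A3.L and MATN4.S, whose spelling kept them out of the list under exact matching, also fell (edgeR, log2 change -2.80 and -2.58, adjusted p = 0.0105 and 0.0236). The mitochondrial share also differed between the fractions, 30.9% in Rho- and 66.2% in Rho+, and its association with these lists was not tested. The connective tissue list was lower in Rho+ in 11 of 11 animals. These include the early bud animal of replicate 3, whose mitochondrial share was higher in Rho-. The housekeeping list, a list for RNA quality, was lower in 11 of 11 animals too. That animal's Rho+ library also had high epidermal genes, so it cannot decide on a link with the mitochondrial share.

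Some signalling genes fell as well. Of 37 WNT pathway targets and feedback genes, 5 fell, and 12 adjusted over the list alone (median -1.41; camera adjusted p = 4.53e-06, adjusted p = 0.114 with an estimated correlation). Beside WIF1 and RNF43 they were SFRP2 and SFRP1, secreted WNT antagonists, at 306 and 135 CPM in Rho- and 80.8 and 56.0 CPM in Rho+ (adjusted p = 0.0139 and 0.0485). FZD2, a WNT receptor, fell as well (adjusted p = 0.0211; 0.121 with the animal as a block, where 414 genes passed). The FGF, BMP, TGF-beta, hedgehog and other growth signals had 4 of 41 lower and 5 adjusted over the list alone (median -1.46, or -1.33 at the bound; camera adjusted p = 3.37e-06, adjusted p = 0.114 with an estimated correlation). The 4 were the feedback inhibitors BAMBI, SPRY2 and DUSP6, with log2 changes of -3.15, -2.90 and -1.94 (SE 0.80, 0.78 and 0.55, adjusted p = 0.0191, 0.0266 and 0.0354), and CHRD, the BMP antagonist chordin (adjusted p = 0.0456; 0.208 with the block). The secretory phenotype list, which holds cytokines, proteases and their inhibitors reported in senescent cells, had 2 of 34 lower and the same number adjusted over the list alone (median -0.99, or -1.05 at the bound; camera adjusted p = 0.000515, adjusted p = 0.114 with an estimated correlation). They were MMP13, a collagenase, at 60.6 CPM in Rho- and 14.4 in Rho+ (adjusted p = 0.0139), and SPARC, which is also in the matrix list. In the proliferation list 1 of 69 fell, the replication helicase subunit MCM7 (adjusted p = 0.0389), which did not pass when adjusted over the list alone. The proliferation median was -0.87 (camera adjusted p = 2.01e-05, adjusted p = 0.429 with an estimated correlation). By stage it was -1.07, 0.19 and -1.53 at the early, mid and late bud and -0.37 at the palette. Of the endothelium and pericyte list, 1 of 30 fell, the vessel wall protein MMRN2 (adjusted p = 0.0258; 0.372 with the block), and 5 adjusted over the list alone (median -1.74, or -1.66 at the bound; camera adjusted p = 0.0112, adjusted p = 0.519 with an estimated correlation, 0.253 with the animal as a block, where 414 genes passed, and 0.108 without early bud Rho+ replicate 3 and palette Rho+ replicate 2). Oxidative phosphorylation had 1 of 43 lower, the cytochrome oxidase subunit COX6C, also adjusted over the list alone (median -0.37; camera adjusted p = 0.0239, adjusted p = 0.604 with an estimated correlation).

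Camera placed the macrophage and monocyte, lysosome and skeletal muscle lists higher in Rho+ over all stages, though not with an estimated correlation. In the macrophage list 3 of 33 rose, CD68, IRF8 and SLC11A1, and 7 adjusted over the list alone, among them MARCO and VSIG4, scavenger and complement receptors of tissue macrophages (median 0.99; camera adjusted p = 1.77e-07, adjusted p = 0.264 with an estimated correlation). MARCO stood at 112 CPM in Rho- and 458 CPM in Rho+, higher in 11 of 11 animals (adjusted p = 0.0643 over all genes). Of 53 lysosome genes 3 rose, and 3 adjusted over the list alone (median 0.54; camera adjusted p = 0.00226, adjusted p = 0.442 with an estimated correlation). ASAH1, acid ceramidase, rose from 120 to 300 CPM (log2 change 1.28, SE 0.31, adjusted p = 0.0163). NPC2, a lysosomal cholesterol carrier, rose from 364 to 704 CPM (log2 change 0.93, SE 0.24, adjusted p = 0.0203), and NEU1, a sialidase, from 60.05 to 140 CPM (log2 change 1.14, SE 0.29, adjusted p = 0.0207; 0.0872 with the animal as a block, where 414 genes passed). Of 24 skeletal muscle genes 3 rose, MYL1, MYLPF and MYH7, which encode myosin chains, and 5 adjusted over the list alone (median 0.94, or 0.69 at the bound; camera adjusted p = 2.76e-05, adjusted p = 0.264 with an estimated correlation). MYL1 stood at 39.7 ± 63.1 CPM in Rho- and 47.4 ± 54.2 CPM in Rho+, with 7 of 11 animals higher. MYLPF stood at 31.2 ± 41.4 and 54.4 ± 36.8 CPM (9 of 11 animals) and MYH7 at 7.18 ± 11.9 and 10.5 ± 10.1 CPM (7 of 11 animals). The log2 change of MYL1, 4.00, averages stage differences that include a palette Rho- group at 0, and was 3.48 at the bound. The macrophage list had a test direction of higher at each stage, but at the palette its median was 0.08 and its mean 1.12, with 19 of 33 members higher and 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0905). The lysosome and muscle lists did not keep the same test direction at each stage, and no difference between stages was tested for lists. At the palette the lysosome median was 0.09, with a test direction of lower (camera adjusted p = 0.934). At the early bud the muscle median was -1.02, with 20 of 24 members lower (camera adjusted p = 0.387). By animal, in exact two-sided sign-flip tests chosen after the values were seen, lysosome genes differed by 0.18 ± 0.49 (higher in 6 of 11 animals, adjusted p = 0.43) and muscle genes by 1.20 ± 2.22 (adjusted p = 0.187), and by fry the lysosome list had an adjusted p of 0.177. Non-mitochondrial counts, which set the depth behind these levels, were 4711000 in Rho+ and 14680000 in Rho-.

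The senescence and cell cycle arrest list did not pass (1 of 23 lower and the same number adjusted over the list alone; median -0.30; camera adjusted p = 0.669), although by fry it was lower (adjusted p = 0.0133; 0.078 with the animal as a block). Its lower member was PLK2, a stress-induced kinase, at 14.2 CPM in Rho- and 1.63 in Rho+ (adjusted p = 0.0103; 0.0819 with the animal as a block, where 414 genes passed). GLB1, the symbol of beta-galactosidase, stood at 37.4 ± 15.8 CPM in Rho- and 77.0 ± 42.3 in Rho+, higher in 10 of 11 animals, without passing (log2 change 1.04, SE 0.34, adjusted p = 0.069). CDKN1A, which encodes the cell cycle inhibitor p21, stood at 9.44 ± 6.70 and 28.2 ± 32.9 CPM (log2 change 1.17, SE 0.82, adjusted p = 0.449; 6 of 11 animals higher). CDKN1B, TP53, MKI67 and LMNB1 did not pass either, with log2 changes of 0.12, -0.47, -1.15 and -1.25 (SE 0.46, 0.33, 0.85 and 0.60, adjusted p = 1, 0.443, 0.487 and 0.226). PCNA.L, a replication clamp gene matched after the values were seen, stood at 205 CPM in Rho- and 81.9 in Rho+ (adjusted p = 0.0596; 0.0344 with the animal as a block). The WNT ligand list did not pass either (camera adjusted p = 0.548). Its 7 tested members did not pass over all genes, and 2 rose when adjusted over the list alone. These were WNT8B, at 0.585 CPM in Rho- and 0.735 in Rho+ (adjusted p = 0.0893 over all genes), and WNT3A, at 0.148 and 2.37 CPM (adjusted p = 0.1 over all genes). Both are near the floor, with a fraction at 0 in 1 and 2 stages. Their log2 changes were 2.32 and 3.94, or 1.78 and 2.78 at the bound. WNT4, WNT9A, WNT10B and WNT11 had adjusted p-values of 0.619, 1, 0.508 and 0.288, and WNT2B, at 0.502 and 1.43 CPM, one of 1. WNT-5A, WNT-5B, WNT6.S, WNT7C.S and WNT8, spellings matched afterwards, had 0.162, 0.838, 0.643, 0.0945 and 0.56.

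Of the lists for other cells and for RNA quality, several moved by some tests. Housekeeping genes were lower by fry (adjusted p = 0.00221) and in 11 of 11 animals (exact two-sided sign-flip test, adjusted p = 0.00659), and neutrophil genes by fry (adjusted p = 0.0165; 0.0663 with the animal as a block, where 414 genes passed) and by animal (adjusted p = 0.0394). By camera these did not pass, and adjusted p was 0.23 for epidermis, 0.564 for erythroid, 0.395 for lymphocyte and for Schwann and nerve, 0.195 for neutrophil and granulocyte, 0.482 for osteoclast and for complement and coagulation, and 0.408 for pigment cell. It was 0.934 for immediate early and heat shock, 0.562 for interferon and antigen presentation, 0.669 for lipid handling, 0.367 for housekeeping and 0.714 for ribosomal protein. Members past the threshold over all genes, and adjusted over the list alone, numbered 2 and 2 for complement, 1 and 1 for each of epidermis, osteoclast and Schwann, 1 and 3 for neutrophil, 2 and 3 for lipid handling, 1 and 2 for housekeeping, and 5 and 5 for ribosomal protein. The epidermis member, KRT18, fell (edgeR, log2 change -1.56, adjusted p = 0.0296, or 0.29 with the animal as a block). The epidermis list itself had a median of 0.99, with 20 of 25 members higher. In the interferon list IFIH1, a sensor of viral RNA, fell (adjusted p = 0.0468; 0.196 with the animal as a block, where 414 genes passed) and did not pass when adjusted over the list alone. The erythroid, immediate early, interferon and ribosomal lists had medians of -0.34, -0.19, -0.02 and -0.06 and a test direction of higher, beside an all-gene median of -0.251; the erythroid median lies below it. Lymphocyte and pigment cell lists had medians of 0.03 and 0.67, means of -0.48 and -0.25, and a direction of higher. Among members that passed, ATP6V0D2, a proton pump subunit of osteoclasts, was higher in 11 of 11 animals (adjusted p = 0.0171; 0.057 with the block). The neutrophil receptor CSF3R was lower in 11 of 11 (adjusted p = 0.033), and so was the nerve growth cone protein GAP43 (adjusted p = 0.0177; 0.106 with the block, where 414 genes passed). APOC1, an apolipoprotein, fell by 2.45 on the log2 scale (SE 0.54, adjusted p = 0.00877). PPIB, a housekeeping gene, fell by 0.87 (SE 0.19, adjusted p = 0.00808; 0.0609 with DESeq2 size factors).

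**Figure D3:**
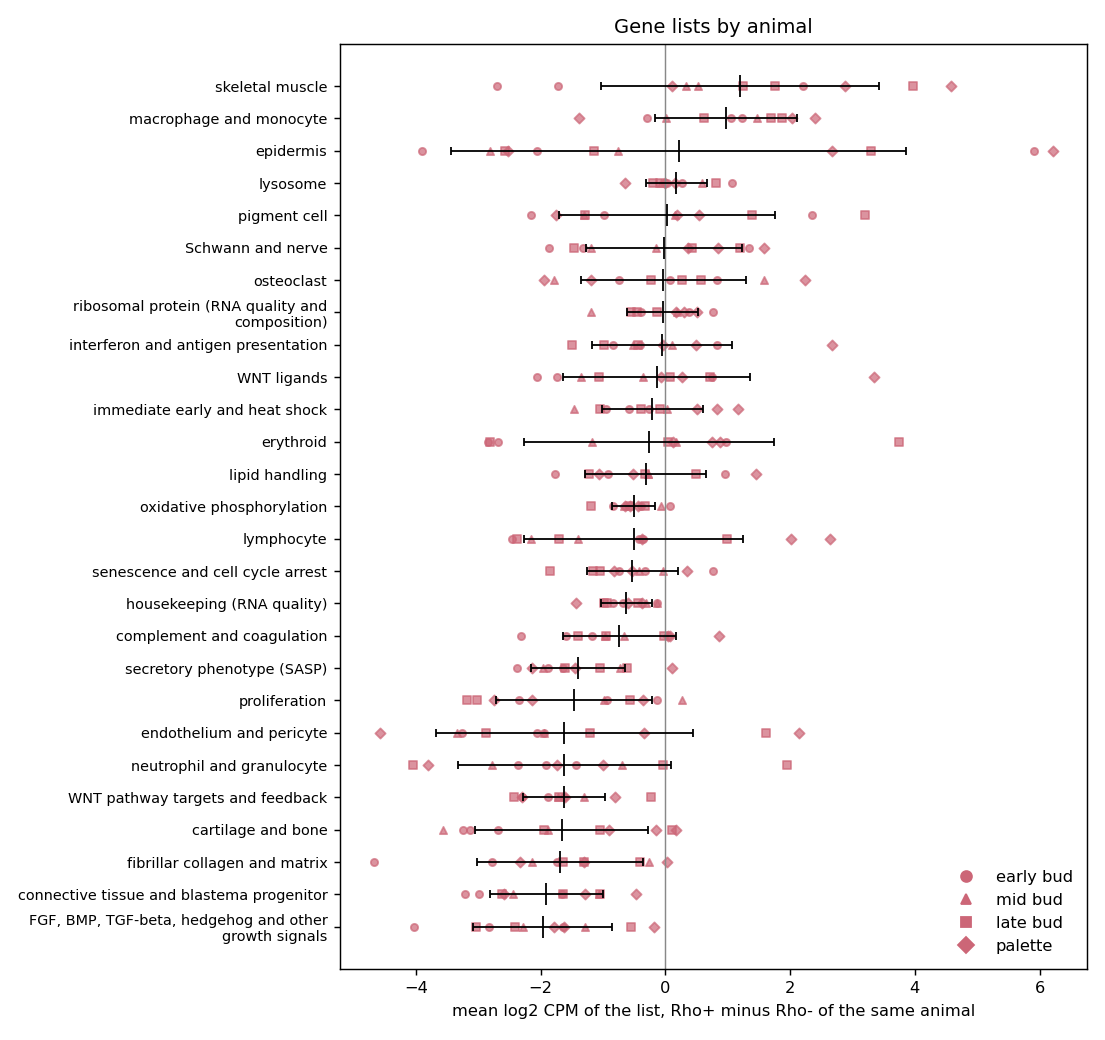
Difference between Rho+ and Rho- of the same animal in the mean log2 CPM of each of the 27 gene lists. Points are animals, marker shape gives the stage, and black bars give the mean ± SD over 11 animals. WNT targets, growth signals, connective tissue genes and housekeeping genes were lower in Rho+ in 11 of 11 animals.

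Many of the loci with the highest change were not conventional genes. Of 969 nuclear loci higher in Rho+, 577 (59.5%) consisted of a lone exon block, against 45 (9.43%) of 477 lower loci and 3533 (15.8%) of 22405 tested. By the rule, the largest rise was ORF2, a retroelement sequence described as a gag polyprotein (arm 6q, 1547514081 to 1547516119), at 0.108 ± 0.206 CPM in Rho- and 5.40 ± 4.78 in Rho+ (adjusted p = 0.00435; 11 of 11 animals). It was followed by a CHK1 locus of 1 exon (AMEX60DD046071, arm 6q, 1411106840 to 1411107050), which rose from 1.14 ± 0.976 to 38.5 ± 21.2 CPM (log2 change 5.32, SE 0.61, adjusted p = 5.81e-05; 11 of 11 animals). The CHK1 symbol is shared by 35 loci, of which 26 were tested, 18 rose and 24 had a lone exon, with a median log2 change of 2.66. Since copies can share reads, the change of any CHK1 or ORF2 locus is uncertain.

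At the early bud, genes of matrix and cartilage were lower in Rho+. PTPRS, a receptor tyrosine phosphatase that binds matrix proteoglycans, fell from 61.7 ± 64.5 CPM in Rho- to 0.231 ± 0.221 CPM in Rho+ (SD, n = 3 each, log2 change -8.05, SE 1.17, adjusted p = 0.0106). COL2A1 fell from 43.8 ± 46.5 to 0.208 ± 0.185 CPM (log2 change -7.65, SE 1.35, adjusted p = 0.0317). CTGF, a matricellular growth factor (arm 4p, 1011902712 to 1011907878), fell from 266 ± 120 to 7.31 ± 5.06 CPM (log2 change -5.19, SE 0.93, adjusted p = 0.0317). The locus with the symbol LEP fell from 40.9 ± 3.67 to 0.476 ± 0.471 CPM (log2 change -6.44, SE 1.23, adjusted p = 0.0471). Each was lower in 3 of 3 animals. Of the fibrillar collagen and matrix list 1 of 44 fell, FBLN1, and 25 adjusted over the list alone (median -2.49, also at the bound; camera adjusted p = 7.98e-30, adjusted p = 0.0315 with an estimated correlation). The connective tissue, growth signal, cartilage and secretory phenotype lists were lower as well, at adjusted p = 0.0315, 0.0315, 0.02 and 0.0334 with an estimated correlation. SFRP2 fell by 4.78 on the log2 scale (adjusted p = 0.0471). In all, 13 genes passed, 1 higher and 12 lower, of 2146 under an unadjusted p of 0.05, and 30 with the animal as a block. Mitochondrial shares at this stage were 23.03, 22.02 and 60.5% in Rho- replicates 1, 2 and 3 and 76.5, 71.5 and 49.8% in Rho+. The count was 1, 1 and 3 without early bud Rho- replicate 1, 2 and 3, 1 without early bud Rho+ replicate 2, and 4 without either mid bud Rho- library. It was 8 and 6 without late bud Rho- replicate 2 and 3, 8 without late bud Rho+ replicate 1, 3 without palette Rho- replicate 1, 2 without palette Rho+ replicate 1 and 36 without palette Rho+ replicate 2. It was 0 with the compared libraries alone or thinned, 763 with DESeq2 and 611 with voom.

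At the mid bud, with 2 animals, no gene passed: edgeR gave 0 genes, with 454 under an unadjusted p of 0.05, and 0 with the animal as a block, against 143 by DESeq2 and 33 by voom. Among loci with a symbol, the smallest p-values belonged to FTH1, the ferritin heavy chain, at 1776 ± 39.8 CPM in Rho- and 6482 ± 1989 in Rho+ (n = 2 each, log2 change 1.87, SE 0.49, adjusted p = 1). CTGF stood at 226 ± 226 and 17.3 ± 2.01 CPM, lower in Rho+ as at the early bud but without passing (log2 change -3.71, SE 1.06, adjusted p = 1). BVES, a muscle membrane protein, stood at 2.23 CPM in Rho- and 0 in Rho+, at least 16.8-fold lower (adjusted p = 1). The mitochondrial 16S_ribosomal_RNA and MGC82347 had log2 changes of 2.62 and 1.91 (SE 0.80 and 0.65, adjusted p = 1). Over all stages these genes did pass the edgeR test. CTGF and BVES were lower in Rho+ (log2 change -3.21 and -6.19, or -5.07 for BVES at the bound, adjusted p = 0.000262 and 0.00134). FTH1, 16S_ribosomal_RNA and MGC82347 were higher (log2 change 1.14, 2.17 and 1.45, adjusted p = 0.00225, 0.00251 and 0.00309). The alternatives were not tallied for them. By camera 9 lists passed at the mid bud, among them macrophage genes higher (adjusted p = 2.39e-05) and matrix genes lower (adjusted p = 9.89e-05), at adjusted p = 0.433 and 0.602 with an estimated correlation.

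At the late bud, a muscle gene was higher in Rho+. LOC115082373, described as parvalbumin beta-like, a calcium buffer of fast muscle (arm 2q, 1249095436 to 1249102165), had 1 count in the 3 Rho- libraries and stood at 46.5 ± 67.9 CPM in Rho+ (n = 3 each, adjusted p = 0.0419; 0.0921 with the animal as a block). The ratio of summed counts, scaled to the effective library sizes, was 4970, with a 95% counting interval from 890 to 196000. LOC113837993, a symbol shared by 96 loci, rose from 0.837 ± 0.579 to 190 ± 220 CPM (log2 change 7.82, SE 1.24, adjusted p = 0.0383; 0.0646 with the block). These 2 were all that passed and fell outside the rule, of 2412 under an unadjusted p of 0.05; with the animal as a block edgeR gave 0, DESeq2 gave 1054 and voom 874. Some lists went as over all stages: camera adjusted p was 8.78e-08 for skeletal muscle and for macrophage genes, both higher, and 1.06e-07 for proliferation genes, lower, each at adjusted p = 0.402 with an estimated correlation. The cartilage and secretory phenotype lists did not pass at this stage (camera adjusted p = 0.527 and 0.234), nor did endothelium, whose test direction was higher (camera adjusted p = 0.932). The count was 0 without late bud Rho- replicate 1, 2 or 3, late bud Rho+ replicate 3, early bud Rho+ replicate 2 or palette Rho+ replicate 3, and 1 without early bud Rho- replicate 1 or 2 or Rho+ replicate 1. It was 31 without early bud Rho- replicate 3, 19 without early bud Rho+ replicate 3, 16 without late bud Rho+ replicate 1, 4 without either mid bud Rho+ library and 6 without palette Rho+ replicate 1.

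At the palette, MYL1 and MYLPF, genes of fast muscle fibres, were found in Rho+ and had no counts in Rho-, while CKM, muscle creatine kinase, stood at 2.94 ± 5.10 CPM in Rho- and 65.4 ± 65.0 CPM in Rho+. Palette Rho- replicates 2 and 3 had the fewest loci detected of the 22 libraries (15764 and 15110). At this stage 7 of 24 muscle, 9 of 15 lymphocyte and 7 of 15 Schwann genes were at 0 in a fraction, and the lymphocyte list was higher in Rho+, with 13 of 15 members (camera adjusted p = 0.0365, adjusted p = 0.525 with an estimated correlation). MYL1 (arm 9q, 326820127 to 326833617) stood at 0 CPM in the 3 Rho- libraries and 33.1 ± 36.9 CPM in Rho+ (n = 3 each), at least 1200-fold higher (adjusted p = 0.0133). MYLPF, the regulatory myosin light chain of fast fibres, stood at 0 and 36.9 ± 52.3 CPM, at least 1340-fold higher (adjusted p = 0.0182). BEND2, a BEN domain protein, and RASAL3, a Ras regulator of blood cells, were at 0 in Rho- and at least 588-fold and 559-fold higher in Rho+ (adjusted p = 0.0229 and 0.021; 0.199 and 0.158 with the animal as a block). RNF43, the diphthamide synthesis gene DPH5, the splicing factor assembly gene GEMIN8 and WDR24, a regulator of mTOR, were at 0 in Rho+ and at least 136-fold, 176-fold, 115-fold and 110-fold lower (adjusted p = 0.0268, 0.0404, 0.0465 and 0.0404; 0.224, 0.21, 0.227 and 0.224 with the block). Skeletal muscle genes rose in 3 of 24 and in 3 adjusted over the list alone (camera adjusted p = 0.00125, adjusted p = 0.525 with an estimated correlation). Epidermal genes were higher as a list (camera adjusted p = 0.0206, adjusted p = 0.57 with an estimated correlation). Their mean log2 CPM was 4.31 in palette Rho+ replicate 2, a library that stands apart by its epidermal genes, and -1.12 and 1.22 in replicates 1 and 3. In total 164 genes passed, 130 higher and 34 lower, of which 38 had no counts in a fraction (32 and 6); with the animal as a block 17 passed, 15 of them shared. The count was 3, 0 and 0 without palette Rho- replicate 1, 2 and 3, and 390 without palette Rho+ replicate 1. It lay between 58 and 109 without early bud Rho- replicate 1 or 2, any mid bud library, any late bud Rho- library, or late bud Rho+ replicate 2 or 3, and was 6 with the palette libraries alone.

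The stage dependence of the difference asked whether Rho+ and Rho- cells diverge differently as the blastema matures, and 2 muscle genes passed. MYL1 stood at 109 ± 87.6 CPM in Rho- and 17.9 ± 11.9 in Rho+ at the early bud, and at 53.3 ± 25.3 and 50.7 ± 20.7 at the mid bud. It stood at 1.15 ± 1.13 and 89.1 ± 93.4 at the late bud, and 0 and 33.1 ± 36.9 at the palette (adjusted p = 0.0315; 0.0234 with the animal as a block). LOC115082373 stood at 33.6 ± 18.7 and 10.2 ± 7.88 CPM at the early bud and at 0 and 15.6 ± 3.91 CPM at the palette (adjusted p = 0.0315). MYH7, PTPRS, BEND2, SLC17A9 and CLN5 came next and did not pass (adjusted p = 0.147, 0.252, 0.302, 0.302 and 0.302). There were 1632 genes under an unadjusted p of 0.05, and 4 passed with the animal as a block. Across 10269 genes, which are not independent replicates, Pearson correlations between stage effects ran from 0.132 to 0.347. Leaving out a library gave 0 calls for early bud Rho- replicate 1 and 3, all early bud Rho+ libraries, mid bud Rho- replicate 1, both mid bud Rho+ libraries, late bud Rho- replicate 2, late bud Rho+ replicate 1, all palette Rho- libraries and palette Rho+ replicate 1 and 3. It gave 1 call without mid bud Rho- replicate 2 or late bud Rho+ replicate 3, and 4 without late bud Rho- replicate 3.

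**Figure D4:**
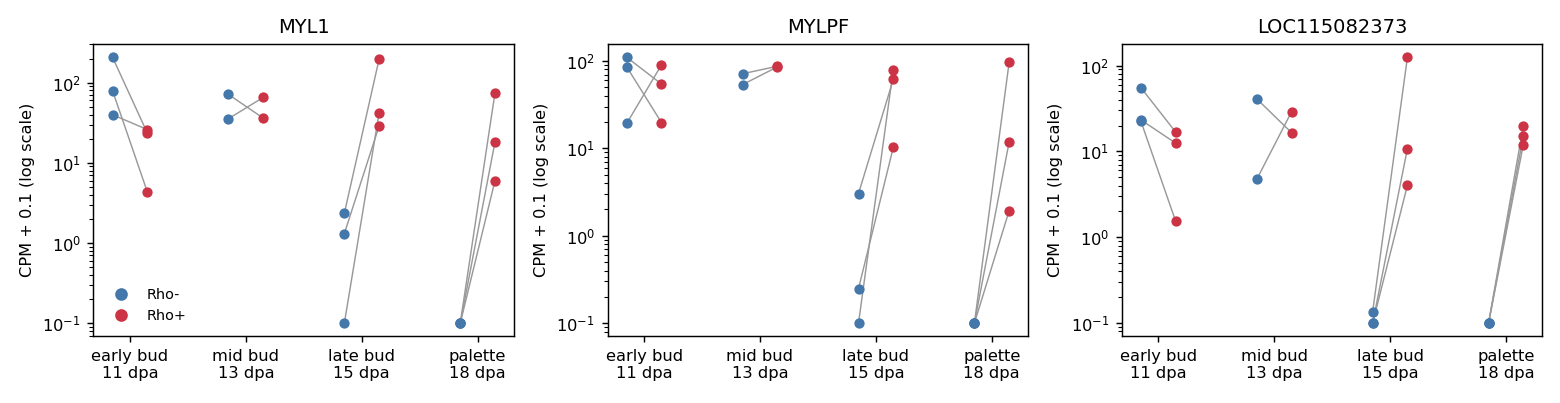
Levels of MYL1, MYLPF and LOC115082373 in each library by stage, as CPM + 0.1 on a log axis. Points are libraries, blue for Rho- and red for Rho+, and grey lines join the paired libraries of an animal; the 3 palette Rho- libraries had no counts of these genes.

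Between the early bud and the palette, the muscle genes MYL1 and LOC115082373 fell in Rho- cells. MYL1 stood at 109 ± 87.6 CPM at the early bud and 0 at the palette (n = 3 each), at least 3950-fold lower (adjusted p = 0.00869), and LOC115082373 at 33.6 ± 18.7 CPM and 0, at least 1220-fold lower (adjusted p = 0.0206). MYH7 and MYLPF, at 23.2 and 71.7 CPM at the early bud, also had no counts at the palette but did not pass (adjusted p = 0.0501 each). FN1 stood at 1771 ± 459 and 312 ± 229 CPM (adjusted p = 0.235). Palette Rho- replicates 2 and 3 had the fewest loci detected of the 22 libraries, 15764 and 15110, with 19086 in replicate 1, against 21752, 23673 and 17393 in early bud Rho- replicates 1, 2 and 3. As lists, chosen for this comparison after the values were seen, 11 passed by camera. Muscle genes were lower and oxidative phosphorylation and proliferation genes higher at the palette (camera adjusted p = 6.07e-08, 4.59e-08 and 1.22e-07, adjusted p = 0.219, 0.219 and 0.272 with an estimated correlation). Markers of other cells were lower together with muscle: macrophage (median -1.12, or -0.97 at the bound), lymphocyte (median -6.71, or -4.51 at the bound, 7 lower adjusted over the list alone), complement and epidermis (median -1.79), at camera adjusted p = 8.35e-05, 0.0017, 0.000417 and 0.0225 (adjusted p = 0.413, 0.219, 0.269 and 0.632 with an estimated correlation). Immediate early, secretory phenotype, WNT ligand and matrix genes were also lower (camera adjusted p = 0.00435, 0.00991, 0.0299 and 0.044; adjusted p = 0.219, 0.272, 0.219 and 0.632 with an estimated correlation). These 2 genes were all that passed, of 3021 under an unadjusted p of 0.05; LOC115082373 fell outside the rule. The count was 1 without early bud Rho- replicate 1 or palette Rho- replicate 2, 5 without palette Rho- replicate 1 or 3, 4 without mid bud Rho+ replicate 2, and 8 without late bud Rho- replicate 3. It was 7 without early bud Rho+ replicate 3, and 6, 12 and 15 without palette Rho+ replicate 1, 2 and 3. It was 0 with the compared libraries alone, 1025 by DESeq2 and 600 by voom.

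In Rho+ cells, cartilage genes were higher at the palette than at the early bud. COL2A1 rose from 0.208 ± 0.185 to 98.9 ± 91.4 CPM (n = 3 each, log2 change 8.83, SE 1.41, adjusted p = 0.0138), and COL9A3.L, a collagen IX chain, from 0.141 ± 0.126 to 111 ± 63.1 CPM (log2 change 9.55, SE 1.57, adjusted p = 0.0138). MATN4.S, a matrilin, had 1 count at the early bud and stood at 107 ± 106 CPM at the palette (adjusted p = 0.0138). The ratio of summed counts, scaled to the effective library sizes, was 3070, with a 95% counting interval from 550 to 121000. PTPRS rose from 0.231 ± 0.221 to 35.2 ± 5.16 CPM (log2 change 7.25, SE 1.14, adjusted p = 0.0138). LEP rose from 0.476 ± 0.471 to 73.8 ± 60.3 CPM (adjusted p = 0.0245) and AVIL, an actin-binding protein, from 1.51 ± 1.34 to 74.9 ± 87.9 CPM (adjusted p = 0.0299). AMMECR1, a gene of little known function, fell from 28.7 ± 12.7 to 0.281 ± 0.304 CPM (log2 change -6.71, SE 1.26, adjusted p = 0.0299). Lists of cartilage, connective tissue and matrix genes were higher (camera adjusted p = 0.00018, 7.4e-06 and 1.71e-06, adjusted p = 0.0796, 0.401 and 0.537 with an estimated correlation). Macrophage and lysosome genes were lower (camera adjusted p = 7.4e-06 each, adjusted p = 0.537 and 0.403 with an estimated correlation). In all 14 genes passed, 12 higher and 2 lower, of 3298 under an unadjusted p of 0.05; 6 of the 13 early bud calls between fractions were among them, and both comparisons use the early bud Rho+ libraries. The count was 0, 3 and 1 without early bud Rho+ replicate 1, 2 and 3, 0, 105 and 22 without palette Rho+ replicate 1, 2 and 3, 31 and 33 without mid bud Rho+ replicate 1 and 2, and 8 without late bud Rho- replicate 2. It was 0 with the compared libraries alone, 1796 by DESeq2 and 5 by voom.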

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

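MYL1 and LOC115082373 were singled out because the difference between fractions varied by stage, and the naming of LOC115082373 was the choice made after the result was seen. MYL1 (adjusted p = 0.0315) and LOC115082373 (adjusted p = 0.0315) were lower in Rho+ than in Rho- at the early bud and higher at the late bud and the palette. Chance could not be excluded for the count of stage-dependent genes, since 2 of the 40 regroupings of animals, the real one included, gave as many, with a real count of 2 and a highest other count of 2.

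For MYL1, muscle cells or fibres caught in some libraries could be the source. Its level followed the mean of 23 other muscle genes in Rho- (r = 0.803, p = 0.00355, 0.709 without the 2 farthest libraries) and less closely in Rho+ (r = 0.472, p = 0.142), between the bounds of 0.6 and 0.3 set for the test, so this explanation and a change within cells cannot be told apart. The omission of any of 17 libraries ended the call (adjusted p from 0.0541 without mid bud Rho- replicate 2 to 0.18 without early bud Rho+ replicate 1), and it held without early bud Rho- replicate 2, late bud Rho- replicate 1 or 3, late bud Rho+ replicate 2 or palette Rho+ replicate 2 (0.0385, 0.027, 0.0067, 0.0343 and 0.0293). That met the condition written for a single library as the cause, yet so many omissions single out no one library, and the reading was changed to undecided after this was seen. The biological explanation, that the kind of cell taking up the dye changes with stage, stays open and untested, and so does the low complexity of palette Rho- replicates 2 and 3 (15764 and 15110 loci detected) as a source of the zero counts there, although MYL1 was also low at 1.15 ± 1.13 CPM in late bud Rho-, with 18366 to 24069 loci detected.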

How the results depend on the processing

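The tests without mitochondrial counts, with thinned counts, with 2 or 3 libraries left out and with looser symbol matching were chosen after the data were seen. Over all stages 1462 genes passed, against 2567 without a filter, 946 with a stricter filter, 414 with the animal as a block, 2768 by DESeq2 and 3553 by voom, and 143 to 1673 with a library left out. At the early bud 13 passed, against 1 with DESeq2 size factors, 141 without a filter, 3 with a stricter one, 30 with the block, 763 by DESeq2, 611 by voom, 0 with the compared libraries alone, 1 without mitochondrial counts, 0 thinned, 29 with 2 libraries left out, and 1 to 36 with 1 left out. The mid bud gave 0 by edgeR (454 at an unadjusted p under 0.05), against 4 without a filter, 143 by DESeq2 and 33 by voom. The late bud gave 2, against 5 with size factors, 103 without a filter, 0 with a stricter one, 0 with the block, 1054 by DESeq2, 874 by voom, 0 with the compared libraries alone, 7 thinned, 31 and 80 with 2 and 3 libraries left out, and 0 to 31 with 1 left out. The palette gave 164, against 689 without a filter, 278 with a stricter one, 17 with the block, 2894 by DESeq2, 347 by voom, 6 with the compared libraries alone, 266 without mitochondrial counts, 253 and 296 with 2 and 3 libraries left out, and 0 to 390 with 1 left out. Stage dependence gave 2, against 219 without a filter, 0 with a stricter one, 4 with the block, 359 by DESeq2, 0 thinned, 0 with 2 or 3 libraries left out, and 0 to 4 with 1 left out. For palette against early bud no animal is in both stages, so the block there is the replicate number, which does not pair the libraries. That comparison gave 2 in Rho-, against 198 without a filter, 6 with that block, 1025 by DESeq2, 600 by voom, 0 with the compared libraries alone, 15 with 2 libraries left out, and 1 to 15 with 1 left out. In Rho+ it gave 14, against 265 without a filter, 9 with that block, 1796 by DESeq2, 5 by voom, 0 with the compared libraries alone, 84 and 39 with 2 and 3 libraries left out, and 0 to 105 with 1 left out. Of the 12 lists over all stages 0 passed with an estimated correlation, and 10 to 12 with a library left out. The ribosomal protein list turned to lower and passed (adjusted p = 0.0155) without mid bud Rho+ replicate 1, and reached 0.992 without mid bud Rho- replicate 2. The cause was not tested, except that left-out libraries and the compared libraries alone reduce the number of samples, and a left-out mid bud library leaves a lone sample assumed to vary like the other groups. Outside the left-out libraries, named genes kept their side of the threshold in 1546 settings, moved past it in 92 and lost it in 195, and lists kept it in 270, gained it in 5 and lost it in 21. Of levels without a test, 311 stayed within 1 SD and 25 moved. There were 43 sign changes in which neither fit passed the threshold. Depth limits genes of low level, since Rho+ libraries held as few as 2587152 non-mitochondrial counts.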

Other observations

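The tests of lists by animal and of macrophage against endothelial genes were chosen after the result was seen. Within animals, WNT targets, growth signals and connective tissue genes were lower in Rho+ in 11 of 11 animals, by -1.63 ± 0.66, -1.97 ± 1.11 and -1.91 ± 0.90 on the log2 scale (SD, exact two-sided sign-flip test, adjusted p = 0.00659 each). Genes of growth arrest did not stand out: the senescence list differed by -0.53 ± 0.73 (adjusted p = 0.066), while proliferation genes were lower by -1.47 ± 1.25 (adjusted p = 0.00989). At the mid bud the proliferation list was not lower, with a median log2 change of 0.19 beside an all-gene median of -0.154. Neutrophil genes, among them the receptor CSF3R, were lower by -1.62 ± 1.71 (adjusted p = 0.0394) and macrophage genes differed by 0.97 ± 1.14, higher in 9 of 11 animals without passing (adjusted p = 0.0528). Housekeeping genes were lower by -0.62 ± 0.40 in 11 of 11 animals (adjusted p = 0.00659) as well.

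Early bud Rho+ replicate 3 and palette Rho+ replicate 2 had high epidermal genes and took 30.5 and 23.3% of non-mitochondrial counts from loci with a LOC number, against 15.1 ± 1.45% in Rho- (n = 11). Early bud Rho- replicate 3 had a mitochondrial share of 60.5%, within the range of the Rho+ libraries.

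By camera over all stages, connective tissue and matrix genes were lower and macrophage genes higher in Rho+. With an estimated correlation camera gave adjusted p = 0.114, 0.151 and 0.264, so these results were lost there. After thinning to equal non-mitochondrial counts the matrix median was -0.79 with an all-gene median of 0.12, beside the reported -1.14 and -0.25. The matrix list thus stayed below all genes at equal counts. Thinning keeps each gene's expected share of the counts, so this test cannot decide on depth. Without the 2 epidermal libraries the matrix median was -0.98 with an all-gene median of -0.47, so the list stayed below all genes but the distance shrank. It still passed at the preset correlation (camera adjusted p = 1.43e-08). At that correlation flips of labels within animals passed a median of 6 lists, so passing cannot decide whether those libraries are the whole cause. The prediction was that a lower share of connective tissue cells alone would move macrophage and endothelial genes alike. Macrophage genes moved above endothelial ones by 2.59 ± 2.82 (exact two-sided sign-flip test, p = 0.0166, 9 of 11 animals). The endothelial list also holds pericyte genes, which a loss of connective tissue cells could lower, so the test cannot decide on this explanation. A larger share of macrophages in Rho+, whether senescent or taking up the particle, could give the pattern and stays open and untested. The fraction also goes with a lower yield of non-mitochondrial counts in 10 of 11 animals, which the design cannot separate from it.

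Single-exon loci were higher in Rho+. For those without a symbol, the 50 loci with the largest excess held 66.4% of the excess summed over 5628 loci. The 1990 loci with a deficit were left out of that sum. The share argues against background spread evenly over loci, but background reads gathered on a few loci could give it too. After thinning to equal non-mitochondrial counts, 81.6% of the single-exon loci called higher (471 of 577) stayed called higher. The all-gene median moved from -0.25 to 0.12, which favours that outcome. Thinning keeps each locus's expected share of the counts, so this test cannot decide on depth. For the broad low-level remainder, loci nearly silent in Rho- gained 0.577 times as many reads per kb with a lone exon block as with several (bootstrap interval 0.552 to 0.602), below the range of 0.67 to 1.5 set for background and above the bound of 0.5, so genomic background cannot be told apart from transcripts. That test capped each locus at 10 reads, a limit set before its result but absent from the written prediction, and without it the ratio was 0.481, for which no interval was computed. No biological explanation was tested, and reads shared among copies stay open.

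For the count of genes over all stages, 1 of 60 flips of labels within animals, the real one, gave as many, with a real count of 1462 and a highest other of 8. That argues against fraction labels without any effect. A flip puts the difference between fractions into the spread within groups, so the flips do not bear on the size of the count. Chance could not be excluded for the count of lists, where 3 of 60 gave as many, with a real count of 12 and a highest other of 15. The 10 splits of 3 against 3 libraries are too few for a share under 0.05. The real count and the highest other, with the number of splits as large, were 13 and 0 (1) at the early bud, 2 and 0 (1) at the late bud, 164 and 5 (1) at the palette, 2 and 1 (1) for palette against early bud in Rho-, and 14 and 33 (2) in Rho+.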
